A study of Mus musculus with 6 samples.

How the data were processed

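Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in CD4 T cells of C57BL/6 mice. Naive CD4 T cells were left untreated or grown under Th17 conditions for 48 h or 72 h. Per the labels' protocols, Th17 conditions were plate-bound antibodies to CD3ε and CD28, which stand in for antigen and costimulation, together with TGF-β and IL-6. Each of the 3 conditions has 2 libraries, labelled as independent biological replicates. The libraries were size-selected for short fragments and sequenced on an Illumina HiSeq instrument, per the labels' protocols.

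The data analysed here are 3 lists of peaks, 1 per condition. Whether a list was called on 1 library or on the pooled reads of both is not given in the sources used here. The submitters' processing notes name Bowtie2 2.3.4.1, SAMtools 1.9, MACS2 2.2.6 and deepTools, and the mouse builds GRCm38 and mm10, which are names of the same assembly. The calling threshold, the treatment of duplicates, the filters and whether reads were shifted for the Tn5 cut are not given in the sources used here. The lists have no header and hold a chromosome, a start, an end and a peak name. The deposited 48 h and 72 h lists also hold a whole-number score per peak, which is the authors' own value and whose scale no header states. In those lists it runs from 30 upward. The naive list holds no score. Scores were used to describe, rank or filter peaks within 1 list and were not compared between lists. Peak names carry running numbers, and 4446 numbers are absent from the naive list, 4606 from the 48 h list and 4321 from the 72 h list, so the numbering runs beyond the peaks analysed here, and the reason is not given in the sources used here. In the naive list, 1 line without values was left out.

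Peaks of the 3 lists that shared at least 1 bp were merged into regions. A region was counted as present in a condition when a peak of that condition's list lay in it. For a pair of conditions, a region was called gained when it was present in the later condition and absent from the earlier, and lost in the opposite case. These words describe the lists. A missing peak shows that no peak passed the authors' calling and filtering, not that the chromatin was closed. Read depth is unknown because the lists give neither reads nor signal, so a count test across libraries could not be run and no p-value is given. Shares of regions have exact Clopper-Pearson 95% binomial intervals, which cover counting error only and not the spread between cultures.

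Genes were taken from a RefSeq table of assembly GRCm38.p6 with 21900 protein-coding genes. It gives the start and end of each gene without strand or exons. A region was assigned to each protein-coding gene whose body, with 10 kb on each side, it overlapped, so neighbouring genes can share regions. A total of 16632 genes had at least 1 region. A region whose middle lay within 1 kb of either end of a protein-coding gene was called near a gene end, which stands in for a promoter because the transcription start could not be told from the transcript end. A region was said to lie inside a gene when its middle did, and the distance of a region to a gene is the gap between their nearest ends. Coordinates are 1-based on GRCm38/mm10.

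Before the data were examined, 16 gene lists were fixed, covering Th17 lineage genes, genes of naive and quiescent T cells, T cell activation genes, BATF, IRF and AP-1 factors, the IL-6 and STAT3 pathway, TGF-β signalling and regulatory T cell genes, Th1, Th2 and Tfh genes, growth and proliferation genes, pan T cell genes, housekeeping genes, markers of B cells, of myeloid cells and of CD8 and NK cells, and a background list of genes of unrelated tissues and of erythroid cells. For each list the balance was the number of distinct gained regions minus the number of distinct lost regions at its members. The balance was placed among those of 10000 random gene lists of the same size, matched member by member on the number of regions per gene. Where fewer than 30 genes had the same number of regions, the range of numbers was widened until 30 did. Genes with very many regions, such as Foxp1, were therefore matched loosely. A list was said to stand apart when its balance lay outside the central 95% of the random balances. This describes these peak lists and is not a test across cultures.

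The genes named in the text follow a rule fixed at the same time. In each of the comparisons of naive cells with 48 h and 72 h, up to 4 members of each list with the most unequal numbers of gained and lost regions were eligible, together with the 5 genes with the most gained and the 5 with the most lost regions among all protein-coding genes. List members without any region were eligible where a count called for them. Single regions were the 10 with the highest 72 h score among those at 48 h and 72 h but not in naive cells, and 10 naive-only regions, taken by width because the naive list has no score. Regions at Il17a, Il17f, Il23r, Lef1 and Foxp3 are given by position, and some other loci of the rule are not reported here. Further list members named as examples were chosen after their values were seen.

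The alternatives changed the overlap that counts as shared, the merging distance, the peak width, the chromosomes, the stringency and length of the lists, the evidence needed for a gain or loss, the flank around genes and the distance to gene ends. Where an alternative needed a naive score, peak width took its place, which was chosen after seeing the data. The planned comparison of transcription factor motifs needs genome sequence, which was not used here. The planned distance to transcription start sites, the leaving out of single replicates and the fit with replicate as a block were not run for the reasons given above.

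The steps were tested on simulated data. After the classes of the regions had been shuffled and the peak ends trimmed at random, the class totals after merging matched for 81315 of 81315 regions. The simulated peaks were merged regions with slightly trimmed ends, so this outcome was fixed by construction and checks the code only. For the comparison of naive cells with 72 h, 4 of 100 simulated lists of 15 genes without any planted difference stood apart. When 20% of the lost regions of a list were turned into gains, 18 of 50 lists stood above the random lists, and when 40% were turned, 43 of 50 did. These lists were drawn from 11447 genes. Lists without a planted difference set random genes against random genes, so their low count follows from the definition of standing apart. It checks the code and does not calibrate the fixed lists. Shuffling also removed any tendency of regions at the same gene to change together. The counts for planted differences may therefore be too favourable for the fixed lists. The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.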

Results

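Accessible chromatin was mapped by ATAC-seq in naive mouse CD4 T cells and in the same kind of cells after 48 h and 72 h of culture under Th17 conditions. Th17 cells are the helper T cells that make the cytokines IL-17A and IL-17F. The design has 2 libraries for each of the 3 conditions, and 1 peak list per condition was analysed, so differences between conditions have no replicate check. The naive list held 53259 peaks that covered 19.83 Mb with a median width of 273 bp. The 48 h list held 40624 peaks over 12.64 Mb with a median width of 234 bp, and the 72 h list held 53926 peaks over 17.68 Mb with a median width of 239 bp. The median peak score, as the authors deposited it, was 69 at 48 h and 76 at 72 h.

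Merging gave 81315 regions. Of these, 20812 (25.6%, 95% interval 25.3 to 25.9%) were present in all 3 conditions, and 23435 (28.8%, 28.5 to 29.1%) were present in naive cells only. A further 10674 regions (13.1%, 12.9 to 13.4%) were shared by 48 h and 72 h and absent from naive cells, and 14876 (18.3%, 18.0 to 18.6%) were seen at 72 h only. The remaining classes were smaller. They comprised 5579 regions in naive cells and at 72 h but not at 48 h, 3848 at 48 h only and 2091 in naive cells and at 48 h but not at 72 h. With the widest 40624 peaks of each list, a setting chosen after seeing the data, 2718 regions were in naive cells and at 72 h but not at 48 h. Regions present in all 3 conditions were wider and had higher scores than the others. Their median 72 h score was 133, against 91 for regions shared by 48 h and 72 h, 51 for regions at 72 h only and 52 for regions in naive cells and at 72 h but not at 48 h.

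**Figure D1:**
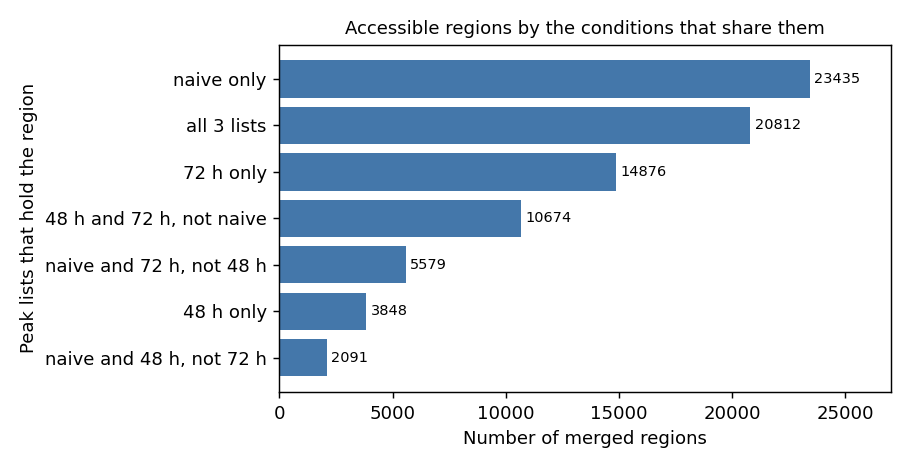
Horizontal bars give the number of merged regions (x axis) for each combination of peak lists that holds them (y axis). The naive-only class (23435 regions) and the class in all 3 lists (20812 regions) are the longest bars.

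The comparison of naive cells with 48 h asks how the accessible regions differ early in Th17 culture. At 48 h, regions were gained at Th17 lineage genes and lost at genes of the naive state. Il17a, which encodes the signature Th17 cytokine, had 0 regions in naive cells and 3 at 48 h. Rora, a nuclear receptor of Th17 cells, went from 19 to 27 regions with 17 gained and 9 lost, and Il1r1, the receptor for IL-1, from 2 to 5 with 5 gained and 2 lost. Foxp1, a factor that maintains T cell quiescence, went from 78 to 33 regions with 11 gained and 56 lost. Lef1, a TCF-family factor of naive T cells, went from 27 to 9, Satb1, a chromatin organiser, from 19 to 5, and Bach2, a repressor of effector genes, from 49 to 29.

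Over the whole genome, 14522 regions were gained at 48 h, 29014 were lost and 22903 were shared. Lost regions made up 55.9% of the naive regions (95% interval 55.5 to 56.3%), and gained regions made up 38.8% of the 48 h regions (38.3 to 39.3%). Among protein-coding genes, 8169 had more lost than gained regions and 3237 had more gained than lost. The genes with the most gained regions were Inpp4b with 20, Atxn1 and Rora with 17 each, Lrba with 15 and Hivep3 with 14. Those with the most lost regions were Foxp1 with 56, Bach2 with 31, Maml2 and St8sia1 with 29 each and Wwox with 27. Inpp4b also lost 26 regions, and such high counts come from genes that hold many regions. The 48 h list is the shortest of the 3, and with the widest 40624 peaks of each list, a setting chosen after seeing the data, 16470 regions were gained and 18756 lost. With equal numbers of peaks, the remaining excess of losses can only come from 48 h peaks sharing a merged region more often.

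Of the 16 gene lists, 1 stood above and 1 below their random gene lists at 48 h. At the Th17 lineage genes, 52 regions were gained and 32 lost, a balance of 20, where the central 95% of random lists ran from -49 to -4 and 0 of 10000 random lists reached the observed balance. Of its 18 members, 11 had more gained than lost regions and 2 had more lost than gained, among them Il23r, which encodes the receptor chain for IL-23, with 4 gained and 8 lost. At the genes of naive and quiescent T cells, 50 regions were gained and 194 lost, a balance of -144 against random lists from -100 to -28, and 0 of 10000 random lists were as low. Of these 18 genes, 16 had more lost than gained regions. Without Foxp1, the largest of them, the balance was -99, at the 0.635th percentile of the random lists. When only peaks at or above the median width of each list were kept, the balance of this list was -41, at the 11.5th percentile of its random lists, and no longer stood apart.

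The other 14 lists lay within the range of their random lists at 48 h. The median random balance was negative for each of the 14, so more lost than gained regions was the usual outcome for random genes too. Their percentiles ran from 18.5 for the pan T cell genes to 95.3 for the IL-6 and STAT3 pathway. The T cell activation genes, induced by signals through the T cell receptor and CD28, had 31 gained and 70 lost regions. Among them Cd44, an adhesion receptor, had 1 gained and 6 lost, Nr4a1, an early response gene, had 0 gained and 5 lost, and Il2ra, the high-affinity IL-2 receptor chain, had 2 gained and 7 lost. The BATF, IRF and AP-1 factors had 15 gained and 20 lost, with Irf4 at 1 gained and 8 lost and Batf3 at 4 gained and 1 lost. The IL-6 and STAT3 pathway had 23 gained and 31 lost, with Jak1 at 8 gained and 13 lost and Cish, a STAT-induced inhibitor, at 3 gained and 0 lost. The TGF-β and regulatory T cell genes had 37 gained and 94 lost, with Tgfbr2, the TGF-β receptor, at 3 gained and 16 lost. The Th1 list had 20 gained and 30 lost, the Th2 list 11 gained and 16 lost, and the Tfh list 14 gained and 41 lost, of which Tox alone had 5 gained and 22 lost. The growth and proliferation genes had 24 gained and 45 lost, the pan T cell genes 27 gained and 83 lost and the housekeeping genes 7 gained and 18 lost. Markers of other cells gave 9 gained and 12 lost for B cells, 6 gained and 14 lost for myeloid cells, 12 gained and 19 lost for CD8 and NK cells and 5 gained and 6 lost for the background list of unrelated tissues and erythroid cells. Other settings put 3 of the 14 lists above their random lists at 48 h, the T cell activation genes with flanks of 50 kb (balance -47) or by nearest gene body (-20), the Th1 genes with flanks of 50 kb (-8) and the BATF, IRF and AP-1 factors without Irf4 (2).

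The comparison of naive cells with 72 h asks how the accessible regions differ after the longer culture. At 72 h, Il17a had 5 regions and Il17f had 3, with 0 in naive cells for both. Ccr6, the chemokine receptor carried by Th17 cells, went from 1 to 6 regions with 6 gained and 1 lost, Il1r1 from 2 to 9 with 9 gained and 2 lost, and Rora from 19 to 29 with 20 gained and 10 lost. Il10 went from 0 to 3 regions and Ccl20, the ligand of CCR6, from 0 to 2. Losses at the naive genes included Foxp1, with 18 gained and 51 lost regions, Satb1, with 1 gained and 14 lost, and Lef1, with 4 gained and 16 lost. Tcf7, which encodes TCF-1, went from 9 to 4 regions.

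Gains and losses were nearly equal in number over the genome, with 25550 regions gained, 25526 lost and 26391 shared. This near equality follows from the nearly equal numbers of regions, 51917 in naive cells and 51941 at 72 h. It therefore does not show that opening and closing of chromatin were in balance. Lost regions made up 49.2% of the naive regions (95% interval 48.7 to 49.6%), and gained regions made up 49.2% of the 72 h regions (48.8 to 49.6%). Of the regions gained at 72 h, 41.8% (41.2 to 42.4%) were already present at 48 h. A total of 5639 protein-coding genes had more gained than lost regions and 6095 had more lost than gained. The genes with the most gained regions were Itpr1 with 26, Atxn1 with 24, Bach2 with 23, Dlg2 with 22 and Wwox with 21. Dlg2, on chromosome 7 from 90476188 to 92449246, went from 4 to 25 regions, and Atxn1, on chromosome 13 from 45549755 to 45964991, from 13 to 35. Those with the most lost regions were Foxp1 with 51, Bach2 with 30, Maml2 and Wwox with 28 each and Ext1 with 26. Bach2 and Wwox stood on both lists.

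At 72 h the same lists stood apart as at 48 h, and both comparisons use the same naive list, so a peak missed there counts as a gain in each. The Th17 lineage genes had 72 gained and 29 lost regions, a balance of 43 against random lists from -32 to 19, and 1 of 10000 random lists reached it. Of the 18 members, 13 had more gained than lost regions, 1 had more lost than gained (Il23r, with 5 gained and 7 lost) and 4 had equal numbers. Il22 had 0 regions in any condition. The genes of naive and quiescent T cells had 75 gained and 176 lost, a balance of -101 against random lists from -59 to 20, and 0 of 10000 random lists were as low. More lost than gained regions were counted at 15 of these 18 genes and more gained than lost at 2, Klf2 and Il6ra. With only peaks at or above the median width of each list, the balance of the naive list was -23, at the 8.86th percentile of its random lists. Without Foxp1 it was -68, at the 0.24th percentile.

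The other 14 lists lay within the range of their random lists at 72 h, and several contained members with opposite balances. Among the BATF, IRF and AP-1 factors, with 20 gained and 13 lost regions in all, Batf3 went from 1 to 8 regions and Batf from 5 to 7, while Irf4 went from 11 to 6 and Irf8 from 5 to 1. In the IL-6 and STAT3 pathway, with 34 gained and 30 lost, the phosphatase gene Ptpn2 had 8 gained and 2 lost and Cish 4 gained and 0 lost, while Il6st, the signalling chain of the IL-6 receptor, had 2 gained and 5 lost. The T cell activation genes had 52 gained and 68 lost, with Nfkb1 at 13 gained and 9 lost and Icos at 3 gained and 7 lost. The TGF-β and regulatory T cell genes had 59 gained and 80 lost, with Tgfbr2 at 7 gained and 14 lost and Smad7, a TGF-β feedback inhibitor, at 2 gained and 6 lost.

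Genes of other helper T cell fates gave small and mixed counts at 72 h. The Th1 list had 27 gained and 28 lost regions, with Cxcr3 and Ccl5 going from 0 to 3 regions each and Il18r1 from 7 to 3, and Ifng had 0 regions in any condition. The Th2 list had 20 gained and 14 lost, with Rad50, which holds the control region of the Th2 cytokine cluster, going from 1 to 5 regions and Gata3, the Th2 master factor, from 8 to 4. The Tfh list had 24 gained and 37 lost, with Tox at 8 gained and 19 lost and Pdcd1, which encodes PD-1, at 4 gained and 1 lost. With flanks of 50 kb in place of 10 kb, the BATF, IRF and AP-1 list (balance 18) and the Th1 list (balance 23) stood above their random lists. With only peaks at or above the median width, the Tfh list (balance -19) stood below its random lists.

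The growth and proliferation genes had 39 gained and 35 lost regions at 72 h, of which Cdk6, a cell cycle kinase, had 13 gained and 6 lost. The pan T cell genes had 36 gained and 72 lost, at the 5.1th percentile of their random lists, with Cd247 at 4 gained and 14 lost and Cd2 at 3 gained and 10 lost. The housekeeping genes had 7 gained and 14 lost. Markers of other cell types did not stand apart. The B cell list had 22 gained and 11 lost, and 16 of the gains lay at Ebf1, which went from 4 to 17 regions. Without Ebf1 the B cell list had 6 gained and 8 lost. The myeloid list had 7 gained and 14 lost, with Itgam going from 7 regions to 1 and Spi1 from 6 to 2, and Csf1r, Lyz2 and Adgre1 had 0 regions in any condition. The CD8 and NK list had 12 gained and 16 lost, and the background list of unrelated tissues and erythroid cells had 9 gained and 8 lost.

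**Figure D2:**
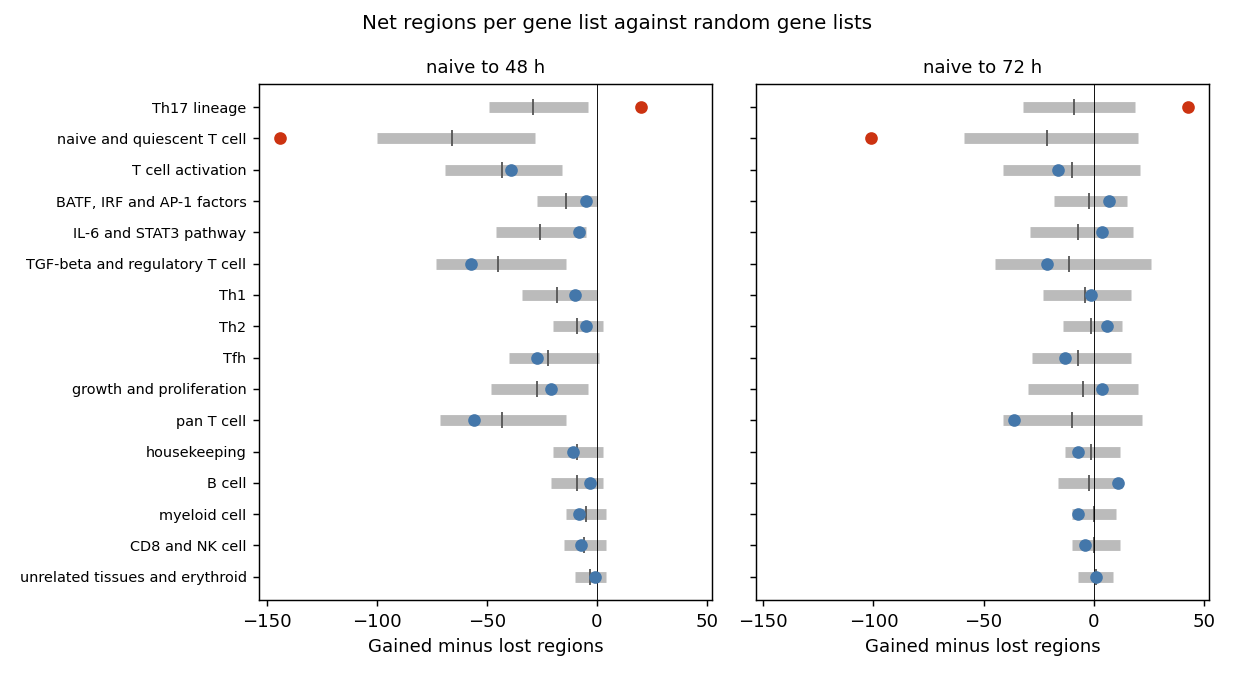
Points give the gained minus lost regions (x axis) of each of the 16 gene lists (y axis) from naive cells to 48 h and to 72 h, grey bars the central 95% and ticks the median of 10000 matched random lists. Red points lie outside the grey bars and blue points inside, and the red points are the Th17 lineage list (20 and 43) and the naive and quiescent T cell list (-144 and -101).

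Single loci showed where these regions lay. The Il17a gene lies on chromosome 1 from 20730905 to 20734496, and its 5 regions at 72 h were all absent from naive cells. The region with the highest score among them, 166 at 48 h and 183 at 72 h, spanned 20740424 to 20740917, outside the gene and 5928 bp from it. A region from 20731635 to 20731858 lay inside the gene and was present at 48 h and 72 h, and a region from 20730744 to 20730997, which overlapped an end of the gene, was present at 72 h only. At Il17f, on chromosome 1 from 20777146 to 20785274, the region from 20791467 to 20791780 was present at both times with a 72 h score of 194, and the other 2 regions were present at 72 h only.

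At Il23r, on chromosome 6 from 67422932 to 67491855, the region with the highest 72 h score, 321, spanned 67459391 to 67459697 inside the gene and was absent from naive cells. Another 7 regions of the same locus were present in naive cells only, so the Th17 culture showed a different set of regions there and not a larger one. At Foxp3, the master gene of regulatory T cells on chromosome X from 7579676 to 7595243, the regions from 7586609 to 7586768 and from 7587624 to 7587794 inside the gene were present in naive cells only. Their naive peaks were narrow, at 160 and 171 bp. Over the genome, 73.6% of naive regions 100 to 170 bp wide and 57.5% of those 171 to 275 bp wide were absent at both times. A small region from 7593438 to 7593543 was present at 72 h only, with a score of 44.

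At Lef1, on chromosome 3 from 131110297 to 131224357, the widest region, 1355 bp from 131207850 to 131209204, was present in all 3 conditions. Of the 27 naive regions of that locus, 16 were lost at 72 h, and the region from 131190708 to 131191306 was lost at 48 h and present again at 72 h with a score of 48. That score lies in the lowest quartile of 72 h scores (30 to 48), where 59.57% of regions shared with naive cells lacked a 48 h peak.

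**Figure D3:**
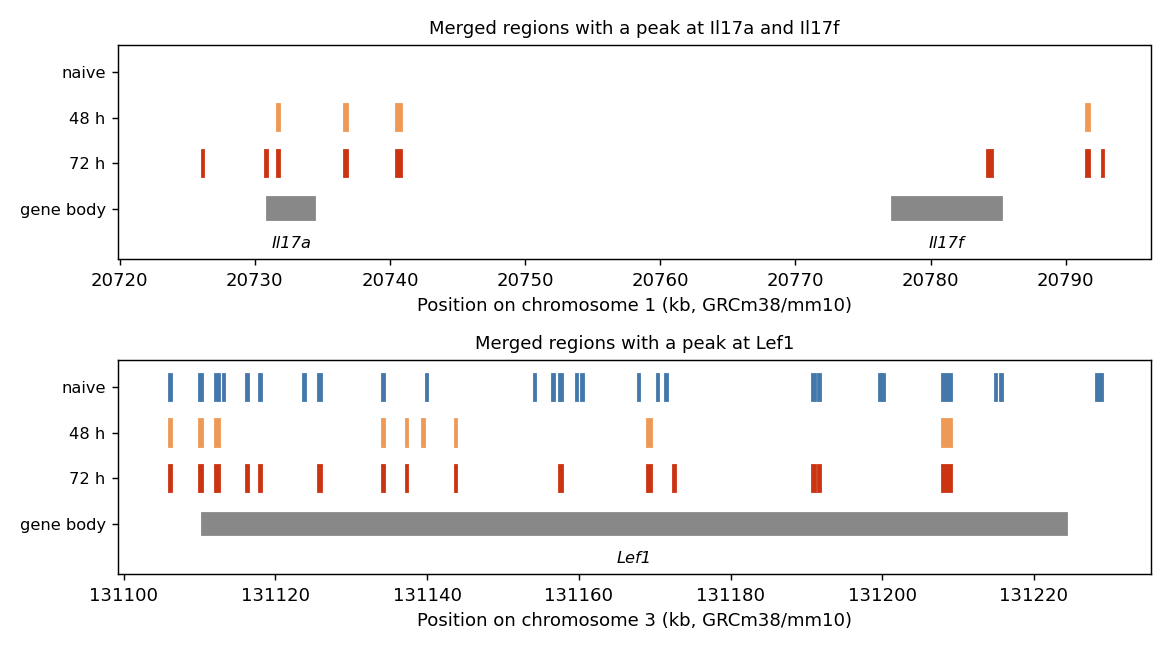
Coloured boxes mark merged regions with a peak in the naive (blue), 48 h (orange) and 72 h (red) lists along chromosomes 1 and 3 (x axis, position in kb), and grey bars mark gene bodies. Very short regions are drawn at a minimum width. Il17a and Il17f have 0 naive regions and 5 and 3 regions at 72 h, and Lef1 has 27 naive regions and 15 at 72 h.

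Among regions present at 48 h and 72 h and absent from naive cells, the highest 72 h scores were found away from the fixed lists. The region with the highest score, 576, lay on chromosome 13 from 108603532 to 108603839, outside any protein-coding gene and 50338 bp from Pde4d. It was followed by a region with a score of 472 on chromosome 3 from 133436317 to 133437470, 26207 bp from Tet2, which encodes a DNA demethylase, and by a region with a score of 464 inside Filip1 on chromosome 9 from 79947272 to 79947764. The other 7 of the 10 had scores from 407 to 460 and lay inside Sgce, Mfap5, Rasal2, Pde1a and Zbtb20 and within 10 kb of S100a10 and Pbp2. The widest naive-only regions lay inside Chl1 on chromosome 6 (1308 bp, from 103510587 to 103511894) and inside Adgrl2 on chromosome 3 (1301 bp, from 148850065 to 148851365), and the other 8 were 1052 to 1255 bp wide.

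The comparison of 48 h with 72 h asks how accessibility differs between the stages of Th17 culture. At the Th17 genes, Ccr6 went from 3 to 6 regions, Il1r1 from 5 to 9, Il17a from 3 to 5 and Il17f from 1 to 3, while Il2, the T cell growth factor gene, went from 5 regions to 1. The Th17 lineage list had 36 gained and 13 lost regions and the list of naive and quiescent T cells 66 gained and 23 lost, and both balances lay within the range of their random lists, as did those of the other 14 lists. Ebf1 went from 8 to 17 regions and Tgfbr2 from 6 to 12. These genes were picked as examples after their values were seen.

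Of the 48 h regions, 31486 (84.1%) were also present at 72 h and 5939 were lost (15.9%, 95% interval 15.5 to 16.2%), while 20455 regions were gained. Gains made up 77.5% (77.0 to 78.0%) of the regions that differed. When the 40624 peaks with the highest score were taken from each list, 11300 regions were gained and 9198 lost, which puts the share of gains at 55.1%. With equal numbers of peaks, the remaining excess of gains can only come from 48 h peaks sharing a merged region more often. In the full lists, 40624 peaks at 48 h gave 37425 regions, and 53926 peaks at 72 h gave 51941. Of the regions gained at 48 h, 73.5% (72.8 to 74.2%) were also present at 72 h. Of those lost at 48 h, 19.2% (18.8 to 19.7%) were present again at 72 h, a class of 5579 regions that fell to 2718 with the widest 40624 peaks of each list.

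Regions that differed between the conditions had low scores more often than shared ones. Among 72 h regions in the lowest quartile of the 72 h score (30 to 48), 67.7% (95% interval 66.9 to 68.5%) were absent from naive cells and 73.5% were absent at 48 h. In the highest quartile (141 to 1103), 23.8% (23.1 to 24.6%) were absent from naive cells, a count of 3102 regions, and 4.02% were absent at 48 h. Of the naive regions in the highest quartile of width, 11.6% were absent at 72 h, against 78.2% in the lowest quartile.

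**Figure D4:**
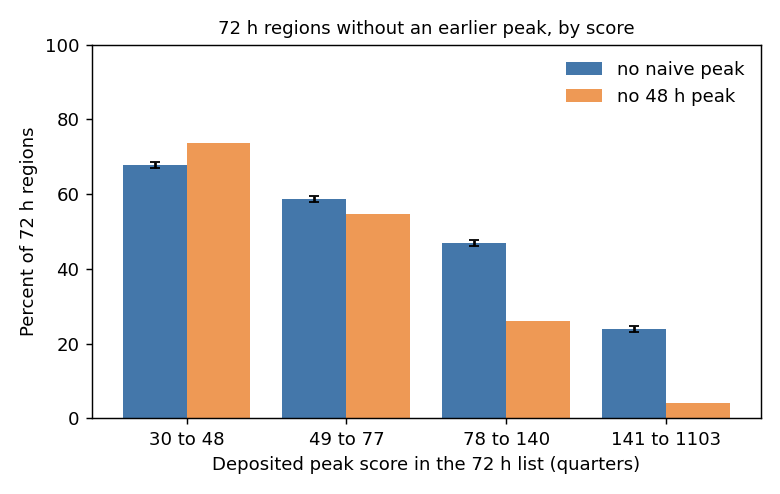
Bars give the percent of 72 h regions (y axis) with no naive peak (blue, with 95% binomial intervals) and with no 48 h peak (orange) in each quartile of the deposited 72 h peak score (x axis). The share without a naive peak is 67.7% in the lowest quartile and 23.8% in the highest.

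The position of regions relative to genes differed between shared and changing regions. Of the regions present in all 3 conditions, 46.5% (95% interval 45.9 to 47.2%) lay within 1 kb of an end of a protein-coding gene, against 10.1% (9.69 to 10.5%) of the naive-only regions and 9.15% (8.61 to 9.72%) of the regions shared by 48 h and 72 h and absent from naive cells. About equal shares of the naive-only regions (50.9%) and of the regions shared by 48 h and 72 h (50.3%) lay inside genes and away from their ends. The remaining 39.0% and 40.5% lay between genes. Regions present in all 3 conditions were also wider, with a median naive peak width of 506 bp against 193 bp for naive-only regions. The shares were not compared at equal width or score, so position and peak strength cannot be told apart here.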

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

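The test in this part, the share of strong 72 h regions without a 48 h peak, was chosen after related values had been seen. Of the 16 gene lists, 6 had balances of opposite sign at 48 h and 72 h against naive cells. The fixed rule named 93 genes, and 3 of these had opposite signs too. Among the further examples in the text, so did Il6ra (-2 and 3) and Il2 (3 and -1). With 1 peak list per condition these differences between the times were not tested across cultures. For the 6 lists the difference equals the balance from 48 h to 72 h, which lay within the range of the random lists in each. The balance of the BATF, IRF and AP-1 factors was -5 at 48 h and 7 at 72 h, 12 regions apart. That of the IL-6 and STAT3 pathway went from -8 to 4, also 12 apart, and that of the Th2 genes from -5 to 6, 11 apart. The growth and proliferation genes went from -21 to 4, a gap of 25, the B cell markers from -3 to 11, a gap of 14, and the background list of unrelated tissues and erythroid cells from -1 to 1, a gap of 2. Several of these signs changed with the setting, such as the 72 h balance of the B cell markers without Ebf1 (-2) and those of the IL-6 and STAT3 pathway (-12) and the growth genes (-10) with flanks of 50 kb. With the widest 40624 peaks of each list, a setting chosen after seeing the data, the balances at 48 h and 72 h were 9 and 7 for the BATF, IRF and AP-1 factors, 7 and 1 for the IL-6 and STAT3 pathway, 0 and 3 for the Th2 genes, -5 and 0 for the growth genes and 3 and 8 for the B cell markers, so the signs were no longer opposite in these 5 lists, in 3 of them because the 48 h balance turned positive. Only the background list had opposite signs, 3 and -2, each reversed. This setting shortens the naive list but not the 48 h list, which by itself raises balances at 48 h, so it does not tell list length from a change in the cells. Among single genes, Itpr1 went from -5 to 11, a gap of 16, Nfkb1 from -2 to 4, a gap of 6, and Ccr4 from -1 to 2, a gap of 3.

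These sign differences stand beside a wider pattern, the smaller number of regions at 48 h than in naive cells or at 72 h. For the 6 lists, matched random gene lists shifted in the same direction, so the shift was not particular to their genes. From 48 h to 72 h the median random balance was 12 for the BATF, IRF and AP-1 factors and 19 for the IL-6 and STAT3 pathway. It was 8 for the Th2 genes, 21 for the growth genes, 7 for the B cell markers and 4 for the background list. For the single genes, a link to the wider pattern was not tested. A candidate explanation is that peaks near the calling threshold were missed at 48 h, for instance because of fewer reads. Of 9923 regions shared by naive cells and 72 h with a 72 h score in the highest quartile, 88 lacked a 48 h peak, 0.887% (95% interval 0.712 to 1.09%), so strong regions were rarely absent at 48 h, as missed weak peaks would give. A transient loss of accessibility confined to weaker regions, which the time course would allow, would give the same value and stays open. The 72 h list alone was also shortened, by score, to the length of the 48 h list. Regions in naive cells and at 72 h but not at 48 h then numbered 3208, against 5579 in the full lists. Those in naive cells and at 48 h but not at 72 h numbered 3684, against 2091. Of the 6 gene lists, only the B cell markers kept opposite signs, -3 and 3. Shortening by itself lowers the counts at 72 h, so these values do not tell list length from a change in the cells.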

How the results depend on the processing

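No paired analysis was possible because each condition has 1 peak list, and leaving out single replicates was not possible for the same reason. Also not run were the motif shares with their alternatives, which need genome sequence, the nearest transcription start, which needs strand, DESeq2, which needs counts, and selections by score that involve the naive list. Settings based on peak width, the nearest gene body and the leaving out of the largest list member were chosen after seeing the data. Depth is unknown, so missed peaks cannot be told from closed chromatin by these values, and the intervals cover counting error only.

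Of the alternatives for the list balances, 183 left the place against the random lists as it was, 7 brought a list outside the range and 2 brought one inside. The sign of the balance changed in 26, in 11 lists, and in 0 of these had the balance stood apart in the setting of the report. In 24 of the 26 the place against the random lists stayed as it was, and the exceptions, Th1 at 72 h with flanks of 50 kb and the BATF, IRF and AP-1 factors at 48 h without Irf4, came to stand above them. Requiring 50% overlap, merging peaks up to 500 bp apart, fixed widths of 500 bp and autosomes alone left every region count within 1.5 times. Halving the lists lowers counts by construction. With peaks at or above the median width, gains and losses were 6658 and 13443 (naive to 48 h), 11410 and 11210 (naive to 72 h) and 9571 and 2586 (48 h to 72 h), with 12087 regions in all 3 lists, 4749 at 48 h and 72 h only, 10533 in naive cells only and 2910 in naive cells and at 72 h only. With scores at or above the median, 48 h to 72 h gave 9771 gained and 2809 lost. When the peak behind a gain or loss had to be at or above the median score, gains were 5389 at 48 h and 9491 at 72 h against naive cells, 3971 regions were at 48 h and 72 h only and 1078 in naive cells and at 72 h only, and 48 h to 72 h gave 4110 gained and 661 lost. When the naive peak had to be at or above the median width, 9142 regions were lost at 48 h, 7325 at 72 h and 6580 at both.

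With lists of equal length, 48 h to 72 h gave 11300 gained and 9198 lost by score, and 11311 gained and 9342 lost by width. At equal length, a difference between gains and losses can only come from how many peaks share a merged region. By width, 18756 regions were lost from naive cells to 48 h and 2718 were in naive cells and at 72 h only. The cause was not tested, since shortening a list also changes which peaks it holds.

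With peaks at or above the median width, the naive and quiescent T cell list had a balance of -23 at 72 h and -41 at 48 h, within its random lists, and the Tfh list stood below them at 72 h with -19. With flanks of 50 kb, 3 lists stood above their random lists, BATF, IRF and AP-1 factors at 72 h (18), Th1 at 72 h (23) and at 48 h (-8) and T cell activation at 48 h (-47). By nearest gene body the T cell activation list stood above at 48 h (-20), and without Irf4 the BATF, IRF and AP-1 list did (2). The cause was not tested. Within 500 bp of a gene end lay 40.7% of regions in all 3 lists, 4.74% of naive-only regions and 5.96% of those at 48 h and 72 h only, and within 2 kb 52.3%, 15.96% and 13.5%, as the distance sets.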

Other observations

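All tests in this part, those of the Th17 lineage list and of the histone genes, and the 9 further gene families were chosen after related values had been seen. The test of the Th17 list for weak peaks uses naive peak width in place of a score, which was chosen after seeing the data, and the gained and lost regions of its genes had been seen before. The chemokine receptor genes, which direct T cell migration, had 38 gained and 37 lost regions from naive cells to 72 h, and the interleukin receptor chains had 67 gained and 75 lost. The KLF factors had 27 gained and 25 lost, the ETS factors 56 and 70, and the SOX factors 36 and 39. The integrin chains, which mediate adhesion, had 62 gained and 78 lost, the DUSP phosphatases, which switch off MAP kinases, 37 and 27, the SLC7 amino acid transporters 18 and 16 and the TNF receptor superfamily 26 and 33. The balances of these 9 families lay within the range of their random lists in each of the 3 comparisons.

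The replication-dependent histone genes, which lie in clusters and are used in S phase, differed from other regions near gene ends between 48 h and 72 h. They were picked from 11 families looked at, and because clustered genes share regions they were set against single regions and not against random gene lists, a comparison that is void for clustered genes such as these and the HOX genes. At 63 histone genes there were 76 regions in naive cells, 69 at 48 h and 64 at 72 h, and 79.6% of their regions lay near a gene end. From 48 h to 72 h, 9 regions were gained and 14 lost, so gains were 39.1% of the changes (95% interval 19.7 to 61.5%), while over all regions near gene ends gains were 75.7% of 3025 changes. From naive cells to 48 h, 13 regions were gained and 20 lost, a share of gains of 39.4% against 30.03% near gene ends and at the 87.6th percentile of draws. From naive cells to 72 h, 7 were gained and 19 lost, a share of gains of 26.9% against 47.0% near gene ends, at the 2.10th percentile of draws and the 5.99th of windows.

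The 48 h to 72 h count lay at the 0.03rd percentile of 10000 draws from changed regions near gene ends. Because the family was picked after its values were seen, this rank describes the pattern and does not exclude a position near gene ends. Among 3003 windows of consecutive changed regions near gene ends, the count lay at the 0.0999th percentile. These windows overlap each other and were not matched to the spacing of the histone clusters. They therefore do not exclude neighbouring regions that change together. Among changes with a score at or above the list median there were 2 gains and 4 losses at histone genes, against 86.8% gains near gene ends in general, which is few. No biological explanation was tested, and the families were searched before this one was singled out, so the pattern stands as a hypothesis.

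The excess of gained over lost regions at Th17 lineage genes from naive cells to 72 h was set against a pair of technical explanations. Gains were limited to 72 h scores at or above the median and losses to naive widths at or above the median. This left 36 gained and 14 lost regions, at the 99.92th percentile, so weak 72 h peaks did not account for the excess. The filter acts only on peaks that are present. A naive peak just under the calling threshold still counts as a gain, so missed naive peaks are not excluded. Without Rora, the largest gene of the list, 52 were gained and 19 lost, at the 99.97th percentile. The data are consistent with the hypothesis that Th17 loci become accessible in this culture, but whether activation alone would do the same stays open, since no activated cells without TGF-β and IL-6 were analysed here, and so does the spread between cultures.

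Chromosomes differed in their balance from naive cells to 72 h. On chromosome 1, 2045 regions were gained and 1782 lost, while on chromosome 17 there were 894 gained and 1274 lost, on chromosome 15 there were 948 and 1276, and on chromosome X there were 473 and 742. Others were near balance, such as chromosome 7 with 1392 and 1361 and chromosome 11 with 1608 and 1567. These chromosomes were picked after their values were seen, and the differences were not tested.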
